A study of Mus musculus with 4 samples.

How the data were processed

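Chromatin accessibility was measured by ATAC-seq in mouse CD8+ T cells from spleen. In this assay the Tn5 transposase cuts and tags DNA that is not packed into nucleosomes, so that reads pile up over open regulatory DNA. The cells came from OTI:Cas9 mice and were electroporated with Cas9 protein bound to a guide RNA. The guide targeted Prdm12 in 2 libraries (sgPrdm12) and was labelled sgNTC in the other 2 libraries. The series' own text calls the control cells non-edited, while the treatment protocol lists sgNTC and sgPrdm12 as the guides of the electroporated complexes; both groups are described here by their guide. Per the labels, replicate 1 of each group belongs to batch 1 and replicate 2 of each group to batch 2. Nothing in the labels says whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

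The deposited table holds 1 set of 3187 peak regions for all 4 libraries, with coordinates on build GRCm38, per the submitters' processing notes. Those notes also name cutadapt, Bowtie2, Picard, MACS2, DiffBind, HOMER and ChIPseeker; their versions, their order and the step that wrote each column are not given in the sources used here. The deposited read counts per peak are whole numbers and were used as raw counts. The table also holds the authors' log2 mean per group, the authors' log2 difference (sgPrdm12 minus sgNTC) and its standard error. In all 3187 rows the authors' log2 difference equalled the difference of the authors' means within a tolerance of 1e-09. In all 3187 rows each authors' mean also followed 1 linear formula of that group's 2 libraries within the same tolerance. The formula was a constant, not reported here, plus a weighted sum of log2(count + 0.5). The weights were 0.499 and 0.465 for sgNTC replicates 1 and 2, and 0.505 and 0.500 for sgPrdm12 replicates 1 and 2, so the deposited log2 means follow from the counts by 1 linear formula per group. The rows are sorted by the count in sgNTC replicate 2, and 1 row has no read in any library. Whether peaks were called per library or on pooled reads is not given in the sources used here.

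Total counts over the table were 28749 and 58068 reads in sgNTC replicates 1 and 2, and 29043 and 20427 reads in sgPrdm12 replicates 1 and 2. The median peak held 7, 15, 7 and 5 reads in that order. Reads outside the listed peaks are not analysed here, so the full sequencing depth is unknown. Whether the table was made from all reads and all called peaks is not given in the sources used here, so having a peak means here having one in this table. Intervals on shares of reads are 95% Wilson intervals and cover counting error only.

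Peaks were annotated with a RefSeq gene table of GRCm38.p6, which is the same assembly as the files' build. The table gives gene spans without strand or exons, so transcription starts were not defined, and exon, intron and UTR positions were not assigned. A peak within 1000 bases of either end of a protein-coding gene was called a gene-end peak and took the gene with the nearest end. Other peaks took the gene whose span they overlapped or lay nearest to. For gene lists, a peak counted for every gene with an end within 1000 bases, and for its assigned gene within 10000 bases. This annotation replaced the promoter class that had been planned, and it was set after the table had been seen.

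The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling, a robust fit, group as the only term, and Benjamini-Hochberg adjustment at 0.05. The filterByExpr function with its default minimum count of 10 kept 1125 peaks. Standard errors of log2 fold changes were taken as the fitted coefficient divided by the square root of F. Normalised read counts are given per 10000 reads in tested peaks, after TMM scaling. Gene lists were tested with limma's camera function (limma 3.58.1) with a preset correlation of 0.01 on voom values, where at least 5 peaks of a list were tested. The 19 lists cover T cell programmes, PRDM and histone methyltransferase genes, a sensory neuron programme linked to PRDM12, and markers of B, myeloid, CD4 and gamma delta T, NK, erythroid and platelet cells. The lists, the main test, the list test and the naming rule were fixed before the data were examined, as were the alternatives except those that the closing section names as chosen later. The rule named any peak of Prdm12 and, because fewer than 5 peaks passed the threshold in either direction, the 5 peaks with the smallest unadjusted p in each direction, plus list members past the threshold. The list members, the highest peaks, the peaks next to Prdm12 and Ints9 fall outside this rule and were chosen for naming after their values were seen. Values of some single list members are not reported here.

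The test was tested on simulated data for sgPrdm12 against sgNTC. Negative binomial counts were drawn for the 1125 tested peaks from the real means and library sizes, with 200 peaks changed, in 10 draws. All peaks had the same dispersion, the common one fitted to the real counts. It recovered 38.1% of 2-fold, 97.8% of 4-fold and 100% of 8-fold changes, and 3.98% of its calls were false. The 95% intervals covered the true value for 95.1% of peaks.

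The replicate numbers pair the libraries, since the labels give same-numbered libraries a shared batch. The correlation over tested peaks between the replicate difference in sgNTC and that in sgPrdm12 was 0.059. Alternatives were the replicate block, DESeq2's size factors, scaling to the total count, no filter, DESeq2 1.42.0 in place of edgeR with and without the block, stricter thresholds, and leaving out each library in turn. No pair of libraries agreed within sampling noise over the tested peaks (chi-square per degree of freedom 1.25 to 1.47), so all 4 were counted separately. The planned comparison of genomic classes among differing peaks had no peaks to compare. The planned motif comparison was not run because no genome sequence was used here.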

Results

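ATAC-seq accessibility was compared between CD8+ T cells given a Prdm12 guide and CD8+ T cells given the sgNTC guide, to find regulatory regions that respond to loss of Prdm12. Prdm12 encodes a PR domain zinc finger protein best known from the development of pain-sensing neurons. The data comprised 2 libraries per group, 1 of each group in each of 2 batches. The 3187 peaks lay on 20 chromosomes and were 247 to 2245 bases wide, with a median of 383 bases. The libraries held 20427 to 58068 reads in these peaks. Reads were found in all 4 libraries at 2416 peaks.

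The peaks lay mostly at genes. Of the 3187 peaks, 1983 (62.2%) were within 1000 bases of an end of a protein-coding gene, and 2311 (72.5%) overlapped the span of the gene assigned to them. The gene-end peak with the highest mean count lay at the predicted gene Gm20783 (chromosome 9, 124424360 to 124425516), with 46 and 122 reads in the sgNTC libraries and 60 and 33 reads in the sgPrdm12 libraries. The peak at Sp1, a general transcription factor (chromosome 15, 102405432 to 102406484), held 52 and 85 reads in the sgNTC libraries and 35 and 21 reads in the sgPrdm12 libraries. The peak shared by Cbx5, a heterochromatin protein, and Hnrnpa1, an RNA-binding protein (chromosome 15, 103239611 to 103240409), held 45 and 79 reads against 39 and 20 reads. The peak between Mrps18b, a mitochondrial ribosomal protein gene, and Ppp1r10 (chromosome 17, 35916204 to 35916743) held 32 and 59 reads against 36 and 28 reads. The peak at Pop7, a subunit of ribonuclease P (chromosome 5, 137502007 to 137502912), held 30 and 62 reads against 33 and 29 reads. These are raw counts from libraries of unequal depth, so they do not give the direction of a difference between groups.

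The tallest peaks in every library were 3 regions within 3000 bases of Rn18s-rs5, an 18S ribosomal RNA pseudogene on chromosome 17 (39846354 to 39848202). The regions spanned 39843397 to 39844951, 39844952 to 39846356 and 39848141 to 39848788, so they lay mostly beside the annotated pseudogene. Together they took 8.41% (95% interval 8.10 to 8.74) and 7.35% (7.14 to 7.56) of the reads in sgNTC replicates 1 and 2. In sgPrdm12 replicates 1 and 2 they took 7.57% (7.28 to 7.88) and 7.43% (7.08 to 7.80). The group means were 7.88% ± 0.75 and 7.50% ± 0.10 (SD, n = 2 libraries each). The pseudogene resembles the ribosomal RNA genes, which are present in many copies. Whether the sequence beside it does too was not examined, so these reads are not assigned to 1 locus. The difference, sgPrdm12 minus sgNTC, was -0.836 percentage points in batch 1 and 0.0848 in batch 2. With 2 libraries against 2, a two-sided exact permutation test of any single value cannot go below p = 0.333.

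The targeted gene itself could not be followed. No peak analysed here was annotated to Prdm12 (chromosome 2, 31635026 to 31655795), so the table gives no check of the edit. The nearest peak was 32077 bases away at Abl1, a tyrosine kinase gene (31687872 to 31688473), with 16 and 10 reads in the sgNTC libraries and 7 and 6 reads in the sgPrdm12 libraries. The next was at Ass1, which encodes argininosuccinate synthase (31470294 to 31470699), with 0 and 4 reads against 5 and 9 reads. These counts are raw and not scaled for depth, and both peaks were below the count filter of the test.

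No peak passed the test for a difference between sgPrdm12 and sgNTC cells. Of 1125 tested peaks, 0 were higher and 0 were lower at an adjusted p of 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the smallest adjusted p was 0.57. At an unadjusted p of 0.05 edgeR returned 57 peaks, 34 higher and 23 lower, where 56.2 are expected by chance. DESeq2's Wald test, run without that filter on 3186 peaks, gave 0 peaks past the adjusted threshold and 28 at an unadjusted p of 0.05. The median absolute log2 fold change was 0.27, below the median standard error of 0.40. Under edgeR's fit to these libraries, large changes were excluded at most tested peaks. The 95% interval lay within 4-fold at 1058 peaks (94.0%), but within 2-fold at only 354 peaks (31.5%). These intervals are not adjusted for the number of peaks and cover only the spread between these libraries. On simulated counts for this comparison the test recovered 97.8% of 4-fold and 38.1% of 2-fold changes, so a 2-fold change at single peaks was often not detectable at this depth. The simulation changed 200 of the 1125 peaks and gave all peaks 1 dispersion. With fewer changed peaks the adjustment is stricter, so recovery may be lower than these values.

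**Figure D1:**
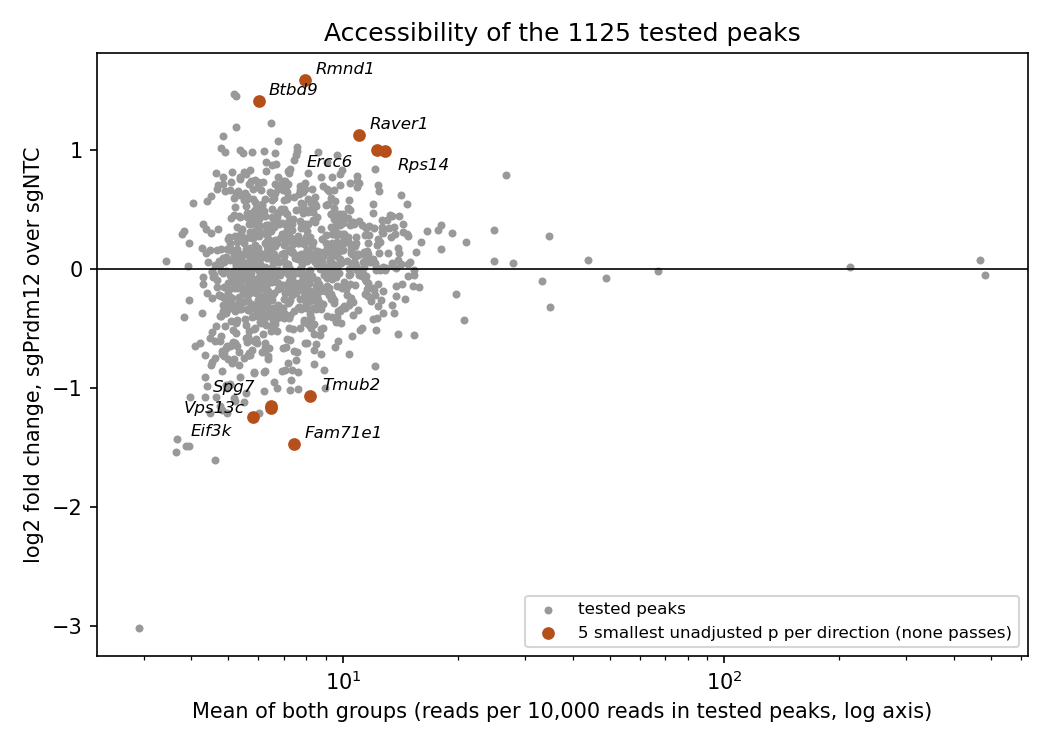
Each point is 1 of the 1125 tested peaks, with the mean of both groups in reads per 10,000 reads in tested peaks on a log axis and the log2 fold change of sgPrdm12 over sgNTC on the vertical axis. The 10 labelled peaks have the smallest unadjusted p in each direction and none passed adjustment, the smallest adjusted p being 0.57.

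Among peaks with higher counts in sgPrdm12 cells, the smallest unadjusted p belonged to Rmnd1, a gene needed for mitochondrial translation. Its peak (chromosome 10, 4432119 to 4432478) had a log2 fold change of 1.58 ± 0.40 (SE; edgeR adjusted p = 0.57). The normalised read count was 3.95 ± 0.96 per 10000 in sgNTC and 11.9 ± 4.62 in sgPrdm12 (SD, n = 2). Next came Raver1, a splicing co-regulator (chromosome 9, 21091504 to 21092062), with a log2 fold change of 1.12 ± 0.33. Ercc6, a factor of transcription-coupled DNA repair (chromosome 14, 32513305 to 32513952), had 0.99 ± 0.30, and Rps14, a protein of the small ribosomal subunit (chromosome 18, 60774336 to 60775080), had 0.99 ± 0.30. A peak inside the Btbd9 span (chromosome 17, 30576064 to 30576436) had 1.41 ± 0.49. The edgeR adjusted p was 0.73 for Raver1, Ercc6 and Rps14, and 0.85 for Btbd9.

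Among peaks with lower counts, the smallest unadjusted p belonged to the peak between Fam71e1 and Emc10, a subunit of an endoplasmic reticulum membrane complex (chromosome 7, 44496004 to 44496493). It held 25 and 36 reads in sgNTC and 6 and 6 reads in sgPrdm12, with a log2 fold change of -1.48 ± 0.46 (edgeR adjusted p = 0.81). Vps13c, a lipid transfer protein (chromosome 9, 67839924 to 67840552), had -1.17 ± 0.42. Spg7, a mitochondrial protease (chromosome 8, 123065180 to 123065780), had -1.15 ± 0.41. The peak shared by Eif3k, a translation initiation factor subunit, and Map4k1, a kinase that restrains T cell receptor signalling (chromosome 7, 28981887 to 28982278), had -1.25 ± 0.45. Tmub2 (chromosome 11, 102284486 to 102285189) had -1.07 ± 0.40. The edgeR adjusted p was 0.85 for Vps13c, Spg7 and Eif3k, and 0.88 for Tmub2. Within batch 1 and batch 2 the log2 ratio was 0.84 and 2.06 at Rmnd1, and -1.91 and -0.85 at Fam71e1.

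**Figure D2:**
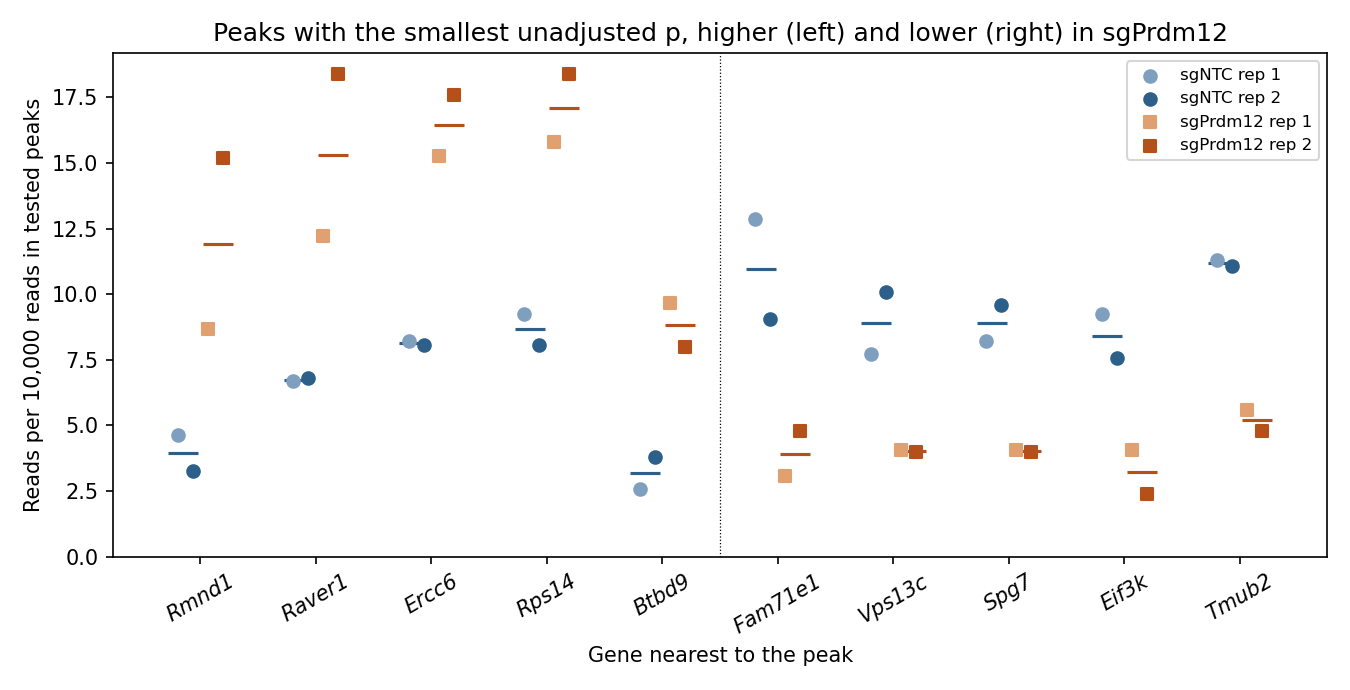
Normalised read counts (reads per 10,000 reads in tested peaks) of each library at the 10 peaks with the smallest unadjusted p; circles are sgNTC and squares sgPrdm12 libraries, and short lines are means of 2 libraries. Rmnd1 averages 3.95 in sgNTC and 11.9 in sgPrdm12, yet no peak passed adjustment over 1125 peaks.

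In the authors' deposited table the 95% normal interval of the log2 difference excluded 0 at 1 of 3187 peaks. That peak lay at Ints9, an Integrator complex subunit gene, and Hmbox1 (chromosome 14, 64949930 to 64950223), with 10 and 22 reads in sgNTC and 2 and 0 reads in sgPrdm12. In the authors' deposited table its log2 difference was -3.18 with a standard error of 1.58. The edgeR test gave it a log2 fold change of -3.02 ± 1.49 and an adjusted p of 0.93.

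No gene of the T cell lists passed the test. Of 457 genes in the 19 lists, 75 had a peak and 23 had a tested peak. Of these, 0 passed edgeR's test over all peaks and 0 passed adjusted over the list alone, where an unadjusted p under 0.05 was found at 57 of 1125 peaks by edgeR and at 28 of 3186 peaks by DESeq2. The cytotoxic effector list, which holds the granzyme genes and Prf1, had no peak for any of its 24 genes, so its accessibility was not compared. Whether the table covers all peaks and reads of these libraries is not given in the sources used here, so a gene without a peak is not shown to be closed. The exhaustion list had 1 gene with a peak (Ikzf2), and the chemokine and homing list had 2 (Ccr2 and Cd44), all below the filter. The 4 cytokine and cytokine receptor genes with a peak (Il15ra, Il18r1, Lif and Tnfsf8) were also below the filter. They held 3.38 ± 1.12 reads per 10000 reads in all peaks in sgNTC and 7.48 ± 3.27 in sgPrdm12 (SD, n = 2), with 5.16 in sgPrdm12 replicate 1 and 9.79 in replicate 2. This comes from 12 and 15 reads in sgNTC and 15 and 20 reads in sgPrdm12, and the difference was not tested.

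Transcription factors that act downstream of T cell activation formed the only list with 5 tested peaks. The AP-1, IRF, NF-kB and STAT list had peaks at 11 of 31 genes, with 0 higher and 0 lower members, and it did not pass as a group (limma's camera test, p = 0.63, and p = 0.67 with an estimated correlation). Its camera direction was down, while its median log2 fold change was 0.01 and its mean was 0.10. Rel, an NF-kB subunit, had a log2 fold change of 0.66 ± 0.40 and Relb had -0.10 ± 0.30. Stat3 had 0.12 ± 0.55 and Irf1, an interferon response factor, had 0.01 ± 0.42. The edgeR adjusted p of these 4 was between 0.97 and 1.00.

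The other lists with tested peaks had 1 to 4 each. In the metabolism list, with peaks at 13 of 32 genes, the 3 tested peaks all had log2 fold changes above 0. The peak shared by Mtor, a growth-controlling kinase, and Exosc10, an RNA exosome subunit, had 0.98 ± 0.39, Srebf2, a regulator of cholesterol synthesis, had 0.56 ± 0.46, and Hk1, a hexokinase, had 0.48 ± 0.45. The smallest p adjusted over the list alone was 0.053 (edgeR). In the T cell receptor list Nfatc3, an NFAT factor, had 0.67 ± 0.47 and Cblb, a ubiquitin ligase that restrains activation, had -0.55 ± 0.40. In the cell cycle list, with peaks at 9 of 30 genes, E2f2 had -1.18 ± 0.62, Cdk4 had 0.22 ± 0.44, Mcm5 had 0.10 ± 0.38 and Cdkn1b had -0.01 ± 0.41. In the PRDM and histone methyltransferase list, with peaks at 7 of 31 genes, Eed, a Polycomb subunit, had 0.41 ± 0.29, Prdm9 had 0.51 ± 0.44, Prdm2 had -0.17 ± 0.41 and Prdm10 had -0.12 ± 0.42. Tcf3 and Klf13 of the lymphocyte lineage list, with peaks at 8 of 31 genes, had -0.39 ± 0.39 and -0.01 ± 0.47. Gadd45b and Sesn1, whose peak is shared with Cep57l1, of the apoptosis and p53 list, with peaks at 9 of 27 genes, had -0.16 ± 0.48 and 0.05 ± 0.38. In the naive and memory list, with peaks at 5 of 21 genes, Bcl6 had -0.07 ± 0.50. The interferon-stimulated list had peaks at 2 of 25 genes and was not tested as a list. The sensory neuron list linked to PRDM12 had peaks for 2 of 30 genes, Ntrk3 and Runx1, neither of them tested. Together they held 3 and 13 reads in sgNTC and 11 and 10 reads in sgPrdm12, or 1.64 ± 0.85 and 4.34 ± 0.78 per 10000 reads in all peaks (SD, n = 2). The value was 1.04 in sgNTC and 3.79 in sgPrdm12 in batch 1, and 2.24 and 4.90 in batch 2, so it was higher in sgPrdm12 in both batches. Runx1 is also in the lymphocyte lineage list, the reads are few and the difference was not tested. Neither a change of a neuronal programme nor its absence is therefore shown.

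**Figure D3:**
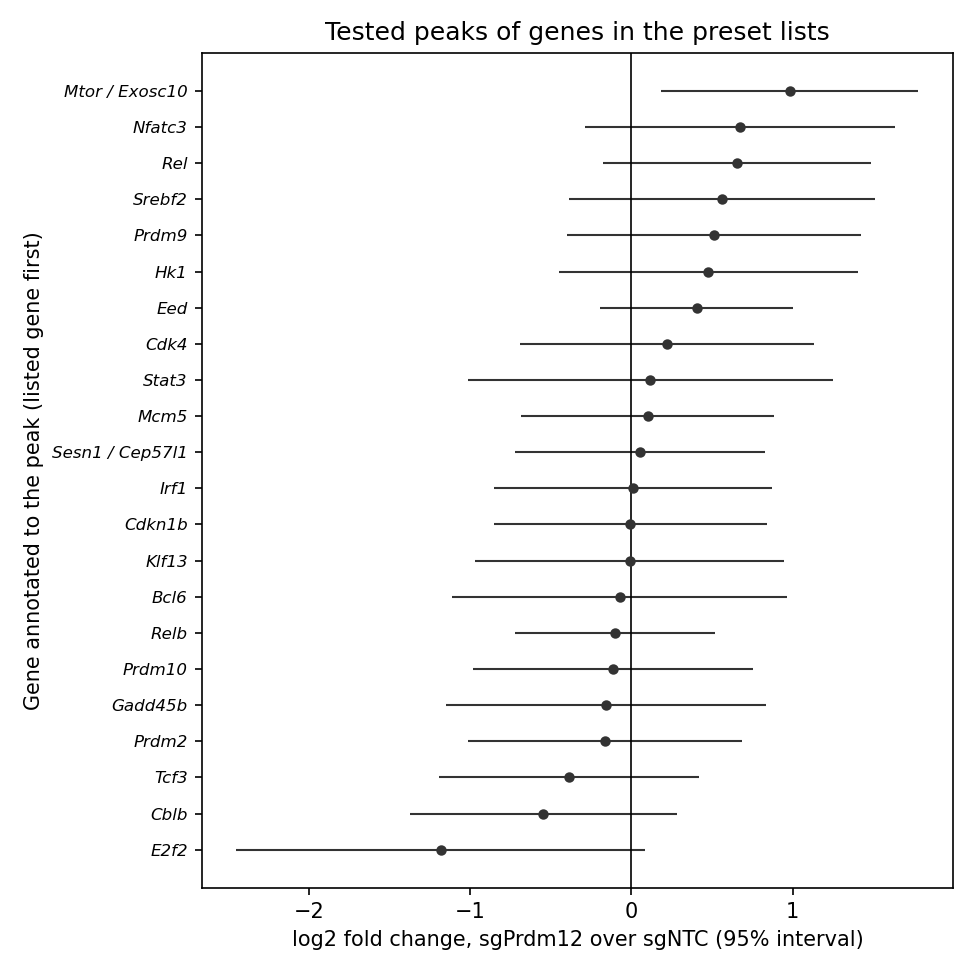
Log2 fold change of sgPrdm12 over sgNTC (points) with 95% intervals (lines) at the tested peaks of 22 genes from the preset lists. The interval includes 0 at all of these except the peak shared by Mtor and Exosc10, whose log2 fold change of 0.98 did not pass adjustment.

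The lists of markers of other spleen cell types had fewer than the 5 peaks needed for the list test. The CD4, regulatory and gamma delta T cell list had peaks at 4 of 19 genes (21.1%) and the myeloid list at 3 of 23 (13%), against 14.2% of all protein-coding genes and none of the cytotoxic effector genes. The B cell list had no peak for any of its 18 genes. The myeloid list had peaks at Ccr2, Cebpb and Xcr1, with 4.25 ± 1.87 reads per 10000 reads in sgNTC and 4.98 ± 2.66 in sgPrdm12. Its value was 5.57 in sgNTC and 3.10 in sgPrdm12 in batch 1, and 2.93 and 6.85 in batch 2, so the direction differed between batches. The list of CD4, regulatory and gamma delta T cell markers had peaks at Bcl6, Ikzf2, Sox13 and Zbtb7b, with 5.35 ± 3.14 reads per 10000 in sgNTC and 8.70 ± 5.0 in sgPrdm12. Its value was 3.13 in sgNTC and 5.16 in sgPrdm12 in batch 1, and 7.58 and 12.2 in batch 2, so it was higher in sgPrdm12 in both batches. These values rest on 9 and 44 reads in sgNTC and 15 and 25 reads in sgPrdm12, and the difference was not tested. Of these marker genes, Ccr2, Bcl6, Ikzf2 and Zbtb7b are also in the T cell lists. The NK list had 1 peak at Klri2, with 2.16 ± 0.60 and 1.11 ± 0.87 reads per 10000, or 1.72 in sgPrdm12 replicate 1 and 0.49 in replicate 2. The erythroid list had 1 peak at Tfrc, with 1.12 ± 1.58 and 0.52 ± 0.73 reads per 10000 (SD, n = 2 libraries in each group).

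The share of reads at gene ends was 70.0% (95% interval 69.5 to 70.5) and 74.3% (73.9 to 74.6) in sgNTC replicates 1 and 2. It was 73.5% (73.0 to 74.0) and 64.9% (64.2 to 65.5) in sgPrdm12 replicates 1 and 2. The group means, 72.1% ± 3.04 and 69.2% ± 6.13 (SD, n = 2), differed by less than the spread between replicates. The difference, sgPrdm12 minus sgNTC, was 3.53 percentage points in batch 1 and -9.43 in batch 2, so it did not hold within batches. Without sgPrdm12 replicate 2 the group difference turned from -2.95 to 1.38 percentage points. The 1040 peaks away from gene ends and below the filter of the main test held 11.6% and 8.10% of the reads in sgNTC replicates 1 and 2, and 8.74% and 17.6% in sgPrdm12 replicates 1 and 2. The filter can leave out peaks with reads in a single library, so the split into tested and untested peaks is not independent of these counts.

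**Figure D4:**
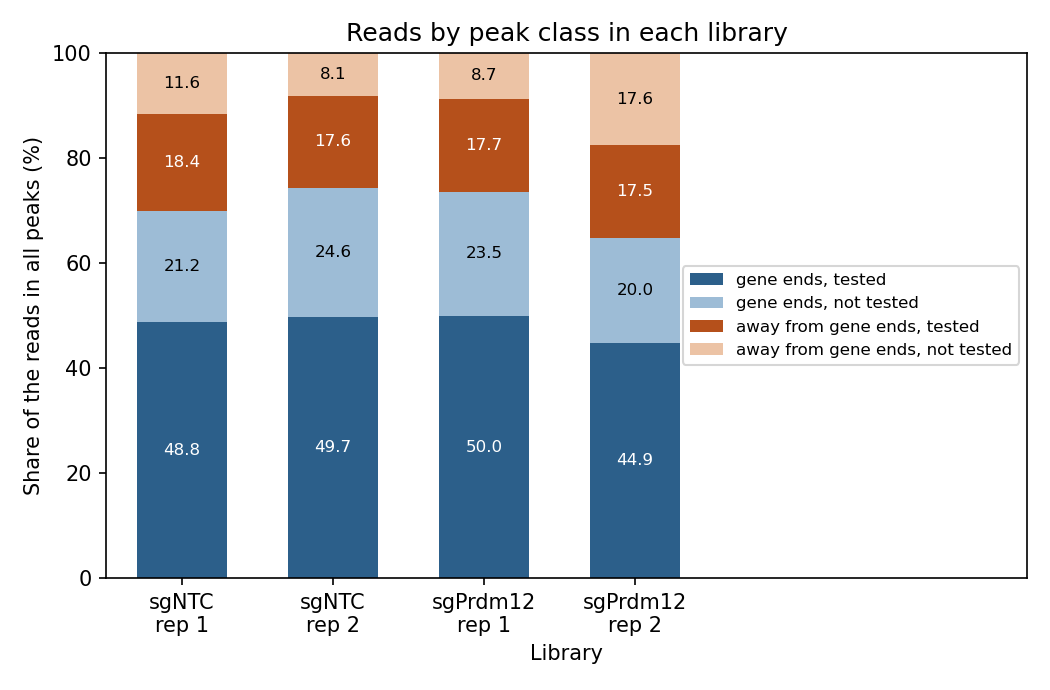
Share of the reads in all 3187 peaks (%) by peak class in each library; gene ends are peaks within 1000 bases of an end of a protein-coding gene, and tested peaks passed the count filter. The class away from gene ends and not tested takes 17.6% in sgPrdm12 replicate 2 and 8.10 to 11.6% in the other 3 libraries.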

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

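The tests of peak selection on single libraries and of an effect common to both sgPrdm12 libraries were chosen after the results had been seen. So were those of the authors' scaling and of the other splits. Those of background and of low counts were fixed before they were run, but after the patterns they address had been seen. Intervals here come from resampled peaks and do not cover the spread between replicates.

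The share of reads at gene ends went in opposite directions in the batches: sgPrdm12 minus sgNTC was 3.53 percentage points in batch 1 and -9.43 in batch 2, each from 1 library per group, and the difference between batches was not tested. The library sgPrdm12 replicate 2 had 176 peaks with at least 5 reads there and at most 2 in the other libraries together, against 109, 14 and 34 in sgNTC replicates 1 and 2 and sgPrdm12 replicate 1. An effect of Prdm12 editing common to both sgPrdm12 libraries would raise the share away from gene ends in sgPrdm12 replicate 1 too. That share minus the share in sgNTC replicate 1 was -3.53 percentage points (-4.49 to -2.47), the opposite direction. This restates the batch 1 value from 1 library each. The rule for excluding such an effect also used the batch 2 value, the one to be explained. It could therefore not have been met, and the effect stays open. In batch 2, 366 peaks were higher in sgPrdm12 replicate 2 than in sgNTC replicate 2 at an unadjusted binomial p under 0.01. Of these, 328 were away from gene ends, and 13 peaks were lower. That test sets 1 library against 1 and covers counting error only. The libraries held 20427 and 58068 reads, and this difference in depth affects how many peaks can pass in each direction. The imbalance of 366 to 13 is therefore no measure of a gain. The 366 peaks had a log2 ratio of -0.042 in batch 1 (-0.24 to 0.14). Peaks that rest on single libraries at low depth would give this. So would any other excess found in sgPrdm12 replicate 2 alone, a higher background included, so the ratio does not tell these apart. A higher background in sgPrdm12 replicate 2 stays open. Over 1787 peaks with a mean of at least 10 sgNTC reads, the share at gene ends in this library was compared with that of sgPrdm12 replicate 1. The difference was -1.65 percentage points (-2.65 to -0.565), an interval that spans the bound fixed before the test was run.

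The log2 ratio of the 366 peaks replaced an earlier form of the same test. That form compared median ratios per peak, came out as an exact tie that decided nothing, and included peaks at Rn18s-rs5. The summed ratio of -0.042, without those peaks, and its bounds were set after that outcome was known, so it carries less weight than a test fixed beforehand.

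The authors' deposited log2 difference was below 0 at 65.8% of the 1983 gene-end peaks, with a median of -0.21, while its median at the 1204 other peaks was 0.13. Whether the authors' scaling between libraries accounts for part of this could not be decided. Over the 961 tested gene-end peaks the median log2 fold change was 0.017 with TMM scaling (-0.013 to 0.050), and -0.17 in the authors' deposited table. TMM scaling was set on the 1125 tested peaks, which include these 961, so a median near 0 there was largely fixed in advance. The values also differ in how the log2 difference was computed from the counts. Whether the log2 of low counts adds to it stays open: the authors' median was higher by 0.16 (0.08 to 0.23) at gene-end peaks with a mean of at least 20 reads than at those under 10, but the share below 0 was 67.3% there against 63.2%. The 164 tested peaks away from gene ends had a median log2 fold change of 0.04 and did not stand apart from the other tested peaks (limma's camera test, p = 0.74, and p = 0.68 with an estimated correlation), which does not exclude a small loss at gene ends. A loss at all peaks alike cannot be seen after scaling between libraries.

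The share of reads at Rn18s-rs5, sgPrdm12 minus sgNTC, was -0.836 percentage points in batch 1 and 0.0848 in batch 2, where the Wilson intervals of the libraries overlapped (7.08 to 7.80 and 7.14 to 7.56), so an opposite direction is not shown, and the difference between batches was not tested.

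The 57 peaks with an unadjusted p under 0.05 were set against the other 2 splits of the 4 libraries into pairs. As many peaks were found in 1 of the 3 splits, the real one, and the highest other split gave 50. The splits are too few for a share under 0.05.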

How the results depend on the processing

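The settings for the share of reads at gene ends, the nearest gene at any distance, and the counts without Rn18s-rs5 or at gene ends alone were chosen after seeing the data. The count of differing peaks was 0 under all 14 alternatives run, with the smallest adjusted p between 0.12 (edgeR without sgPrdm12 replicate 1) and 1.00 (DESeq2 with the replicate block). The stricter thresholds among these 14 were applied to the main fit, which already gave 0 peaks, so their count was fixed in advance. With the replicate block, which pairs the libraries of a batch, edgeR gave 0 peaks, and 47 at an unadjusted p under 0.05. The block changed no other call. Counts at an unadjusted p under 0.05 were 57 of 1125 peaks by edgeR as reported and 109 of 3186 without a filter. They were 28 by DESeq2 and 14 by DESeq2 with the block, both of 3186 peaks, and 40 to 90 of 1484 to 1649 peaks when 1 library was left out. There the lone library of a group was assumed to vary like the other group. The 10 named peaks kept their sign in all 119 values under the alternatives, which choosing them by p favours, and their smallest adjusted p was 0.12. No gene list passed limma's tests in 11 alternatives (smallest adjusted p 0.30). The direction of the AP-1, IRF, NF-kB and STAT list in limma's camera test turned from down to up with the replicate block (adjusted p = 0.65), without sgNTC replicate 2 and without sgPrdm12 replicate 1. The group difference in the share at gene ends was -2.95 percentage points. The mean of paired batch differences equals it by arithmetic, with 1 library per group in each batch, and is no separate check. The group difference was -2.88 within 5000 bases, -3.50 without Rn18s-rs5, and -0.241 over peaks with a mean of at least 10 sgNTC reads. With 1 library left out it was -7.28 to 1.38, above 0 only without sgPrdm12 replicate 2. The settings for genomic class and motifs were not run, since no peak differed and no genome sequence was used, and pseudocounts did not apply to counts. Depth left 2062 of 3187 peaks untested.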

Other observations

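The tests of how often listed genes had a peak and of gene families were chosen after the data were seen, and those of chromosome 2 and of the surroundings of Prdm12 were not. Genes of metabolism and of AP-1, IRF, NF-kB and STAT factors had a peak more often than other protein-coding genes. Of 21900 protein-coding genes, 3114 (14.2%) had a peak in the deposited table. Whether that table holds all called peaks is not given in the sources used here, so the shares describe the table and not all open chromatin of these cells. The metabolism list had 13 of 32 genes (40.6%, adjusted p = 0.0044, two-sided Fisher's exact test over 19 lists), among them Fasn of fatty acid synthesis and Pkm and Hk1 of glycolysis. The AP-1, IRF, NF-kB and STAT list had 11 of 31 (35.5%, adjusted p = 0.024), among them Junb, Fosb, Rel and Relb. The T cell receptor list had 2 of 36 (5.56%, adjusted p = 0.43), the cytotoxic list 0 of 24 (adjusted p = 0.15) and the exhaustion list 1 of 20 (adjusted p = 0.50), none of which passed. Genes differ in length and a peak counts within 10000 bases, so these shares are not corrected for gene size.

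None of 8 sets, chosen mostly by gene symbol, passed the camera test, and the smallest adjusted p was 0.34. The 15 tested peaks of ribosomal protein genes had a median log2 fold change of 0.10 (camera adjusted p = 0.34 over 8 sets), the 17 of Zfp zinc finger genes 0.12 (adjusted p = 0.87), the 11 of splicing factor genes -0.09 (adjusted p = 0.34) and the 5 of complex I genes -0.35 (adjusted p = 0.34). With an estimated correlation the p of the complex I set was 0.25.

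Cas9 cutting can lead to loss of the chromosome part beyond the cut, and this was tested as a hypothesis for chromosome 2 with a prediction written first. Over 48 tested peaks beyond Prdm12 the ratio of summed reads, sgPrdm12 over sgNTC, was 1.06 (95% interval from resampled peaks 0.96 to 1.17), with 1.11 in batch 1 and 1.02 in batch 2. The interval lay above the lower bound fixed beforehand, which argues against loss of the arm in a large share of the cells. It does not cover the variation between replicates. A local change around the targeted gene was tested the same way. Over 11 tested peaks within 5000000 bases of Prdm12 the ratio was 1.01 (0.85 to 1.21), inside the bounds of a 2-fold change either way fixed beforehand. The peaks nearest to Prdm12, at Abl1 and Ass1, were below the filter and not among these, so a change close to the gene was not tested. Of 20 chromosomes, 1 had an interval that excluded 1, the X chromosome, which had 4 tested peaks and ratios of 0.59 and 1.18 in the batches.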
